A study of Caenorhabditis elegans with 3 samples.

How the data were processed

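The series holds 3 ChIP-seq samples of GFP-tagged MEP-1 in whole Caenorhabditis elegans L4 larvae, 1 group with biological replicates numbered 1, 2 and 3 in the labels. Replicates 1 and 2 share a stock source and a library size range of 150 to 350 bp, per the labels; replicate 3 has another source and no size range. Whether replicate 3 differs because of these conditions or by chance cannot be tested with 1 such sample, so values are given per replicate where they matter.

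Per the labels, the authors deposited for each replicate a relaxed region list, made as input for the IDR procedure, a relaxed list of the pooled replicates, and an optimal IDR list, each on builds ce11 and ce10. Peaks were therefore called per replicate and on pooled reads with a control, per the labels. The deposited lists give a score per region (the signal value, whose scale is not stated) and a −log10 q-value, both as the authors' caller wrote them. The deposited −log10 values saturate, so regions were ranked by the score. The aligner, the caller, its settings and the IDR threshold are not given in the sources used here, and the control was not analysed here. Because every relaxed list holds 30000 regions, the number of regions carries no information on depth, and the read depth of a replicate is unknown. A relaxed list reaches into background by design, per the labels, so replicates were compared over equal numbers of their highest-scoring regions.

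All coordinates are ce11 and 1-based. The gene annotation was Ensembl release 115 for assembly WBcel235, which is the same assembly as ce11, and the region coordinates lay within the reference chromosome lengths. Point sources are those of the deposited lists. A gene was called bound when a point source lay from 500 bp upstream to 100 bp downstream of the TSS of any of its transcripts. All tests but that of replicate agreement used the nuclear chromosomes, so 20 mitochondrial regions of the IDR list were left out of them. N, the number of distinct IDR intervals, was 5167, and the top regions of a replicate are its 5167 highest-scoring distinct regions. Regions were shared when they overlapped by at least 1 bp.

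Replicate agreement was compared with 1000 circular shifts within chromosomes and promoter share with 10000. Gene types with at least 10 genes and 24 gene lists were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment (threshold 0.05), with every other protein-coding gene as the background of a list. The per-replicate shares come from each replicate's own top regions. The lists covered MEP-1 partners with NuRD and SUMO genes, DREAM and synMuv B, P granule, meiotic, sperm, major sperm protein, ribosomal protein, translation, histone, proteasome, respiratory chain, stress, collagen, molting, epidermis, heterochronic, vulva, Hox and Polycomb, intestine, muscle, pan-neuronal, nuclear hormone receptor, chemoreceptor, and lectin and F-box genes. The entries mog-6, trp-3 and daf-21 matched no symbol in the annotation and were dropped. The 2080 canonical 6-mers were tested by exact McNemar tests of 100 bp at the point source against 100 bp centred 500 bp away on a randomly drawn side. Differences of medians were tested with 100000 permutations. Genes and regions along a chromosome are not independent, so Fisher's tests of lists were repeated with circular shifts of the bound genes.

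Genes were named by a rule fixed in advance, as were the lists: the 15 protein-coding genes with the highest scores among regions in the top regions of all 3 replicates, the 4 bound members with the highest scores of each list that passed and up to 2 of each other list, mep-1, let-418, hda-1, unc-119, pie-1 and smo-1 whatever their values, the 3 non-coding genes with the highest scores, and the 5 most enriched and 2 most depleted 6-mers by adjusted p. A region was assigned to the protein-coding gene with the nearest TSS within the window and, separately, to the nearest non-coding gene, so a region can be given to one of each.

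Alternatives covered the promoter window (1000 bp upstream to 200 bp downstream, and 200 bp upstream to 100 bp downstream), the upper part of the IDR list by score, overlap of the region in place of the point source, each replicate left out, regions in the top regions of all 3 replicates, the pooled list, the outermost TSS, the background genes, the overlap that counts as shared, the build, and the windows and controls of the 6-mers. Leaving out a replicate kept the IDR regions that overlapped a top region of both other replicates, or for replicate agreement the remaining pair. The IDR list was not made anew, and 67.3%, 67.9% and 72.1% of its regions remained without replicates 1, 2 and 3. These sets are smaller and stricter, so a call lost in them need not stem from the replicate left out. The pooled list's 5229 highest-scoring regions held 5215 of the IDR regions (99.7%), so the pooled alternative is nearly the same set.

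The tests were tested on simulated data. In 100 simulations of 19973 genes, ribosomal protein genes set at 60% bound were called in 100, proteasome genes set at 40% in 90 and collagens set at 3% in 99, and lists with no simulated difference were called in 0.70% of 2000 trials. Of 20 6-mers planted in 5% of 5000 simulated windows, all 20 were recovered, and 15 of 1913 other 6-mers were called. The simulated genes were bound independently of their neighbours, and the simulated windows came from random genomic positions. Neighbours that share a region and the G and C excess of point sources were not simulated. The rates of false calls therefore need not hold for the real lists and windows. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.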

Results

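Binding of MEP-1, a nuclear zinc-finger protein known as a partner of the chromatin remodeller LET-418 and the deacetylase HDA-1, was mapped by ChIP-seq in Caenorhabditis elegans larvae of the L4 stage. The whole animals of strain OP102 carried MEP-1 fused to GFP, and the precipitation was against the tag. There was 1 group with 3 biological replicates, so the comparisons below are between kinds of genes, chromosomes and sequences, not between conditions. Each replicate's list held 30000 regions under a relaxed threshold. The authors' optimal list, which keeps regions that rank reproducibly by the irreproducible discovery rate (IDR), held 5229 regions on build ce11. Read depth was not given in these lists. The authors' score of a region (its signal value) ranks regions within a list only.

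The 5229 regions covered 5167 distinct intervals, with a median width of 404 bp, and 5209 lay on nuclear chromosomes. Chromosome X held 1076 of them, 20.6% of the list, and chromosome III was the most densely covered with 66.6 regions per Mb, against 36.9 on chromosome V. When the 5167 highest-scoring regions of each replicate were compared, replicates 1 and 2 shared 74.9%, replicates 1 and 3 shared 72.3%, and replicates 2 and 3 shared 71.7% (mean 73% ± 1.69, SD over 3 pairs). Circular shifts of the regions along their chromosomes gave 4.13%, 3.81% and 3.89% (one-sided permutation p = 0.001 for each pair, the smallest that 1000 shifts can give). Of the 5229 regions, 3168 (60.6%) overlapped a top region of all 3 replicates. The labels give replicate 3 another stock source and a fragmentation note of its own; 76.9% of the regions overlapped its top regions, against 84.7% for replicate 1 and 83.9% for replicate 2.

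MEP-1 regions were concentrated just upstream of protein-coding genes. Of 5209 nuclear point sources (the position of strongest signal in a region), 2189 (42.0%) lay between 500 bp upstream and 100 bp downstream of an annotated transcription start site (TSS), and each replicate's own top regions gave 42.4% ± 0.72 (SD, n = 3). Circular shifts gave 13.9% ± 0.51, so promoters held 3.02 times the share reached by chance (two-sided permutation p = 0.0002, the smallest that 10000 shifts can give). Promoter points had a median position of −173 bp. Intergenic sequence outside promoters held 33.7% of points, introns held 18.2% and 3′ UTRs held 3.74%, while coding and other exons held 1.61% of points although they make up 21.7% of the nuclear genome. Promoter regions also had higher scores than the other regions, with medians of 118.7 and 99.2 (difference of medians 0.26 on the log2 scale, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give), and the difference was 0.25, 0.22 and 0.17 in replicates 1, 2 and 3. Many annotated worm TSSs are trans-splice sites, so the distances are to the annotated gene start and not to the start of the primary transcript.

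**Figure D1:**
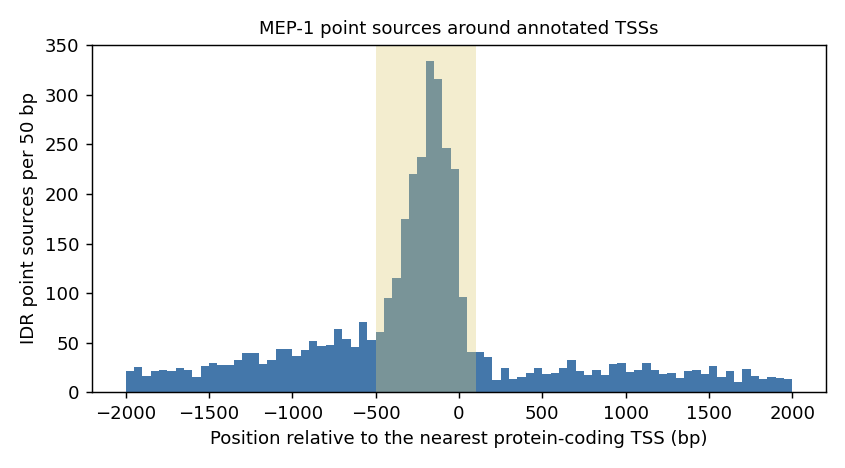
Number of IDR point sources (y axis, per 50 bp) by position relative to the nearest protein-coding TSS (x axis, bp, negative upstream); the shaded band is the promoter window from 500 bp upstream to 100 bp downstream. Points pile up upstream of the TSS, with a median of −173 bp among those in promoters.

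The highest-scoring region at a protein-coding gene present among the top regions of all 3 replicates lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit (chromosome III, 3867023 to 3867830, score 2188). It was followed by the promoters of cdc-48.1, an AAA ATPase of protein degradation (chromosome II, 10563354 to 10563782, score 1689), of Y17G9B.5 (chromosome IV, 4749868 to 4750259, score 1537) and of tasp-1 (chromosome III, 10759025 to 10759486, score 1470). Of the 15 genes with the highest scores, 5 encode ribosomal proteins, namely rpl-3, rpl-15 (score 1438), rpl-35 (1312), rpl-12 (907) and rps-1 (882). The respiratory chain genes cox-5A (chromosome III, 12905011 to 12905409, score 1011) and cox-5B (881), the translation factor gene iff-2 (1073), the spindle and kinetochore gene ska-3 (889), the histone gene his-37 (874), the Pumilio family gene puf-9 (858) and serp-1.1 (853) made up the rest. The histone gene is uncertain, because near-identical copies can share reads. Names were given among protein-coding genes, and the point sources of rps-1 and puf-9 lay nearer to the TSS of a non-coding gene, as did that of the proteasome gene rpn-3 named with its list. Regions with scores under 441 were not compared in this way.

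Over all genes, 2530 of 19973 nuclear protein-coding genes (12.7%) had a point source in a promoter window, and the lists of replicates 1, 2 and 3 taken alone gave 2567, 2470 and 2552. Genes of protein synthesis and turnover and of respiration were bound far more often than other genes. Among cytosolic ribosomal protein genes, 67 of 83 were bound (80.7%, odds ratio 29.6, adjusted exact p = 2.7e-44), and the replicates gave 80.3% ± 0.70 (SD, n = 3). Of these genes, 41 had the TSS nearest to a bound point source, and the rest shared one that lay closer to another gene. Of the translation initiation and elongation genes, 26 of 40 were bound (65.0%, odds ratio 12.9, adjusted exact p = 9.6e-14), led by iff-2, eif-3.C (score 548), eef-1G (460) and eef-1A.2 (443). Of the proteasome genes, 19 of 33 were bound (57.6%, odds ratio 9.42, adjusted exact p = 5.6e-09), with rpn-3 (478), rpn-9 (274), rpt-2 (219) and rpn-11 (214) at the top. Of the mitochondrial respiratory chain genes, 19 of 38 were bound (50%, odds ratio 6.94, adjusted exact p = 1.1e-07), including, after the cox genes, atp-1 (527) and sdha-1 (427). All list tests are two-sided Fisher's exact tests of the IDR list with Benjamini-Hochberg adjustment over 24 lists. The ribosomal call depended on the promoter window: within 200 bp upstream to 100 bp downstream the odds ratio was 1.24 (adjusted exact p = 0.66).

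**Figure D2:**
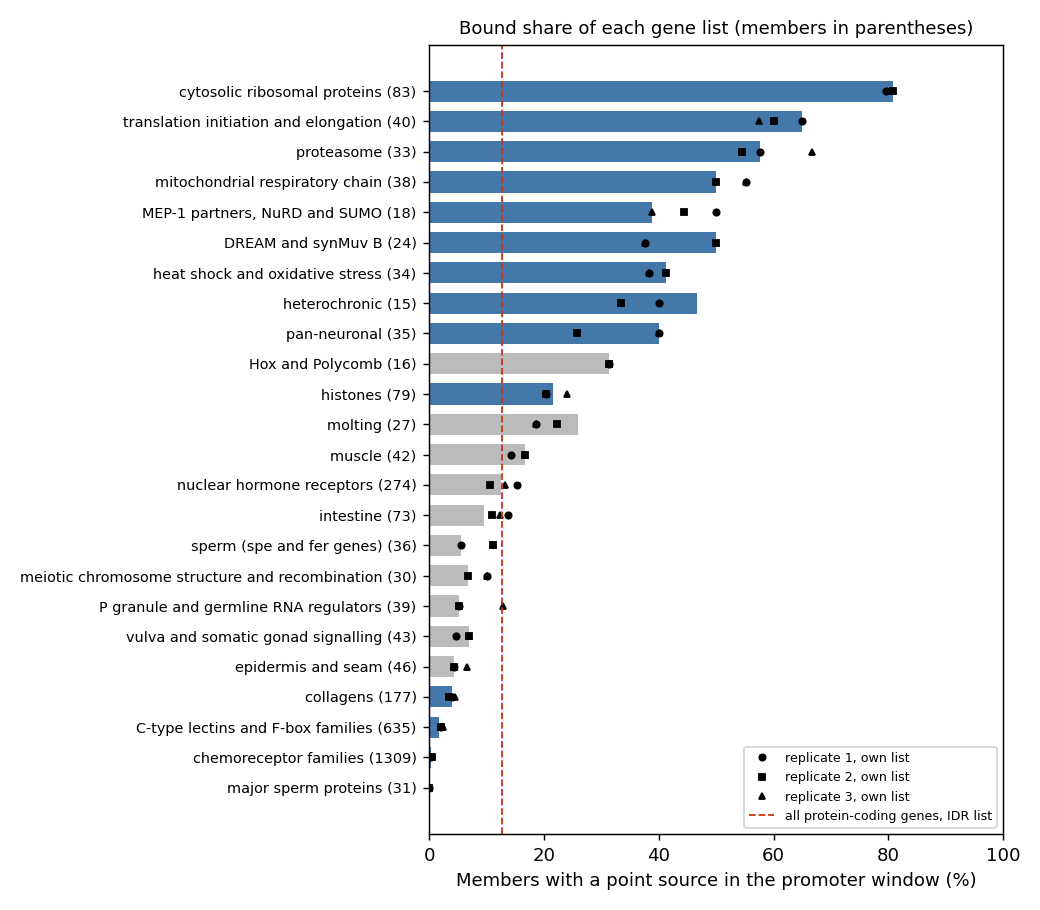
Share of the members of each gene list with a point source in the promoter window (x axis, percent; list sizes in parentheses), for the IDR list (bars, blue where adjusted p is 0.05 or less, grey otherwise) and for the top regions of replicates 1, 2 and 3 (symbols); the dashed line is the share of all protein-coding genes, 12.7%. Ribosomal protein genes stand highest at 80.7%, and none of the 31 major sperm protein genes was bound.

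The list of DREAM and synMuv B genes and that of MEP-1 partners were bound more often than other genes. The share of the DREAM and synMuv B list (50%) equalled that of the respiratory chain genes and lay above that of the heat shock and oxidative stress genes (41.2%). The share of the MEP-1 partner list (38.9%) lay below both. The list of DREAM complex and synMuv B genes also held the synMuv A genes lin-15A, lin-8, lin-38 and lin-56 and the acetyltransferase complex genes mys-1, trr-1 and epc-1. Of its members, 12 of 24 were bound (50%, odds ratio 6.92, adjusted exact p = 3.5e-05), and the replicates gave 41.7% ± 7.22 (SD, n = 3). Leaving out replicates 1, 2 and 3 in turn lowered the odds ratio to 4.90, 5.73 and 4.55 (adjusted exact p = 0.0027, 0.00065 and 0.0039). The strongest were lin-9 (score 452), the retinoblastoma gene lin-35 (361), the acetyltransferase complex gene epc-1 (330) and the E2F gene efl-1 (222). Of the list of MEP-1 partners, NuRD subunits and SUMO pathway genes, 7 of 18 were bound (38.9%, odds ratio 4.40, adjusted exact p = 0.0092). These included mep-1 itself (chromosome IV, 11524262 to 11524599, score 439, rank 139 of the nuclear regions), the splicing helicase gene mog-4 (272), the SUMO-conjugating enzyme gene ubc-9 (210), the NuRD subunit gene dcp-66 (107) and the SUMO gene smo-1 (96.2). The promoters of mep-1 and smo-1 were bound in all 3 replicates. The promoters of the partner genes let-418 and hda-1 were bound in none of the lists, and those of the germline repressor gene pie-1 and of unc-119 were bound in replicate 1 alone and not in the IDR list. The call for the MEP-1 partner list was lost with the narrow promoter window (odds ratio 1.68, adjusted exact p = 0.56) and among genes with no same-strand gene close upstream (3.73, adjusted exact p = 0.051).

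Stress and neuronal genes were also bound more often. Of the heat shock and oxidative stress genes, 14 of 34 were bound (41.2%, odds ratio 4.85, adjusted exact p = 9.2e-05), led by the Hsp70 genes hsp-1 (score 682) and hsp-3 (457) and by the transcription factor genes xbp-1 (299) and atfs-1 (189). Of the pan-neuronal genes, 14 of 35 were bound (40%, odds ratio 4.62, adjusted exact p = 0.00012), with syd-2 (260), the Rab2 gene unc-108 (232), tom-1 (160) and the synaptobrevin gene snb-1 (144) at the top. The protein-coding heterochronic genes, which time larval development, were bound at 7 of 15 (46.7%, odds ratio 6.05, adjusted exact p = 0.0029), led by lin-66 (370), lin-28 (173), alg-1 (155) and lin-14 (152). Among the heterochronic microRNA genes, the promoters of lin-4, mir-48 and mir-241 held a point source and those of let-7 and mir-84 did not. Histone genes were bound at 17 of 79 (21.5%, odds ratio 1.90, adjusted exact p = 0.047), with his-37, his-68 (386), his-32 (286) and his-62 (265) at the top, and as near-identical copies all are uncertain. Circular shifts of the bound genes along the gene order, which allow for neighbours that share a region, gave the histones a permutation adjusted p = 0.059. The histone call was lost under 8 of 16 alternatives, over which the adjusted p ranged from 0.003 to 0.19. Besides the circular shifts, these were the wide promoter window (0.19), overlap of the region (0.058), leaving out replicate 3 (0.070), the lists of replicates 1 (0.099) and 2 (0.063) alone, the background without large families (0.11) and genes with no same-strand gene close upstream (0.094). The heterochronic call was lost under 7 (range 3.8e-07 to 0.52), namely the narrow window (odds ratio 2.06, adjusted exact p = 0.52), the outermost TSS (0.50), leaving out replicate 2 (0.088) or 3 (0.10), regions of all 3 replicates (0.072), and the lists of replicates 2 (0.060) and 3 (0.058) alone. The pan-neuronal call was lost under 4 (range 4.8e-06 to 0.19), namely the narrow window (0.076), leaving out replicate 1 (odds ratio 2.45, adjusted exact p = 0.072), the list of replicate 2 alone (0.061) and regions of all 3 replicates (odds ratio 2.17, adjusted exact p = 0.19). Without replicate 3 it held with a lower odds ratio of 2.69 (adjusted exact p = 0.042).

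Chemoreceptor, lectin, F-box and collagen genes were bound less often than other genes. Of 1309 chemoreceptor genes, 5 were bound (0.382%, odds ratio 0.0245, adjusted exact p = 2.1e-69), among them sri-5 (score 296), srh-16 (269), srh-2 (187) and srt-39 (95.7). Of 635 C-type lectin and F-box family genes, 11 were bound (1.73%, odds ratio 0.118, adjusted exact p = 2.3e-23), with fbxb-72 (376), fbxb-85 (335), clec-126 (247) and bath-36 (176) at the top. Of 177 collagen genes, the main components of the cuticle, 7 were bound (3.95%, odds ratio 0.28, adjusted exact p = 0.00035), and the 4 with the highest scores, col-166 (84.8), col-167 (77.3), col-103 (74.2) and col-10 (63.99), all lay outside the top regions of at least 1 replicate. None of the 31 major sperm protein genes was bound (adjusted exact p = 0.047), and circular shifts gave a permutation adjusted p = 0.14 for this family of near-identical copies. The call was lost under 12 of 16 alternatives, over which the adjusted p ranged from 0.012 to 0.52. The 12 included leaving out replicate 1 (adjusted exact p = 0.18), replicate 2 (0.18) or replicate 3 (0.11). The odds ratio stayed below 1 under all 16 (0.0816 to 0.212), and no member was bound in any replicate's top regions.

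The other tissue and germline lists did not pass the test. Of the P granule and germline RNA regulator genes, 2 of 39 were bound (5.13%, adjusted exact p = 0.30), nos-3 (score 188) and gld-2 (71.0). The meiotic list had 2 of 30 (adjusted exact p = 0.48), brc-1 (346) and rad-51 (208), and the sperm list of spe and fer genes 2 of 36 (0.39), spe-48 (208) and spe-9 (70.7). The Hox and Polycomb list reached 5 of 16 (odds ratio 3.14, adjusted exact p = 0.068), with sor-1 (379) and sor-3 (354) at the top; it passed with the wide promoter window (odds ratio 4.01, adjusted exact p = 0.015) and with overlap of the region (3.61, adjusted exact p = 0.032), and 0.50 was its highest adjusted p over 16 alternatives. The molting list had 7 of 27 (adjusted exact p = 0.11), including myrf-1 (283) and nhr-41 (145), and the muscle list 7 of 42 (0.53), including unc-112 (326) and act-4 (231). In the epidermis and seam list 2 of 46 were bound (0.16), nhr-25 (110) and let-413 (74.8), and in the vulva and somatic gonad signalling list 3 of 43 (0.43), including sur-2 (141) and sys-1 (120). The intestine list had 7 of 73 (0.62), including spp-3 (106) and cpr-4 (98.9), and only in the upper part of the IDR list by score did it pass, as bound less often (odds ratio 0.0809, adjusted exact p = 0.013). The nuclear hormone receptor genes had 34 of 274, 12.4% against 12.7% of other genes, led by nhr-1 (338) and nhr-49 (334).

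Protein-coding genes were bound at 12.7%, against 4.83% of all other annotated genes (odds ratio 2.86, adjusted exact p = 1.2e-203), and tRNA and snoRNA genes were bound more often still. Of 612 tRNA genes, 241 (39.4%) had a point source in the promoter window (odds ratio against all other genes 7.73, adjusted exact p = 1.3e-101), and the replicates gave 38.6% ± 2.29 (SD, n = 3). snoRNA genes followed with 97 of 346 (28.0%, odds ratio 4.47, adjusted exact p = 1.8e-27), then miRNA genes with 44 of 261 (16.9%, odds ratio 2.29, adjusted exact p = 7.4e-06) and snRNA genes with 21 of 129 (16.3%, odds ratio 2.19, adjusted exact p = 0.0028). Other ncRNA genes stood at 9.07% of 7764. piRNA genes (0.905% of 15363, odds ratio 0.0689) and pseudogenes (1.17% of 2128, odds ratio 0.128) were bound less often, and lincRNA (23 of 194), antisense RNA (6 of 100) and rRNA genes (0 of 20) did not pass. The tests of gene types were not repeated with circular shifts, so neighbouring genes that share a point source were counted as independent. The 241 bound tRNA genes rested on 217 point sources. A point source also counted for every gene type with a window that held it. The rarely bound piRNA genes are a large part of the backgrounds of these tests. With them left out, a comparison added after the data were seen, the odds ratios were 5.17 for tRNA genes (adjusted exact p = 9.4e-70), 2.99 for snoRNA genes (2.5e-16), 1.54 for miRNA genes (0.020) and 1.30 for protein-coding genes (4.4e-12), and the snRNA call was lost (1.47, adjusted exact p = 0.16). The direction for other ncRNA genes depended on this choice, with an odds ratio of 1.15 (adjusted exact p = 0.0027) against all other genes and of 0.69 (4.8e-17) without the piRNA genes. Against all other genes the call was also lost in the upper part of the list (1.10, adjusted exact p = 0.11) and in the list of replicate 1 alone (1.08, adjusted exact p = 0.088). The 3 non-coding genes with the highest scores were C18A11.13 (X, region 8036020 to 8036912, score 1172) and the spliced leader RNA genes sls-2.1 (II, 5844575 to 5845209, score 1091) and sls-2.4 (I, 4171929 to 4172661, score 892). tRNA and snRNA genes, the spliced leader genes among them, are uncertain because near-identical copies can share reads. The miRNA call was lost with the narrow promoter window (odds ratio 1.22, adjusted exact p = 0.49), while lincRNA genes passed without replicate 1 (1.68, adjusted exact p = 0.043) and with the wide window (1.64, adjusted exact p = 0.019).

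**Figure D3:**
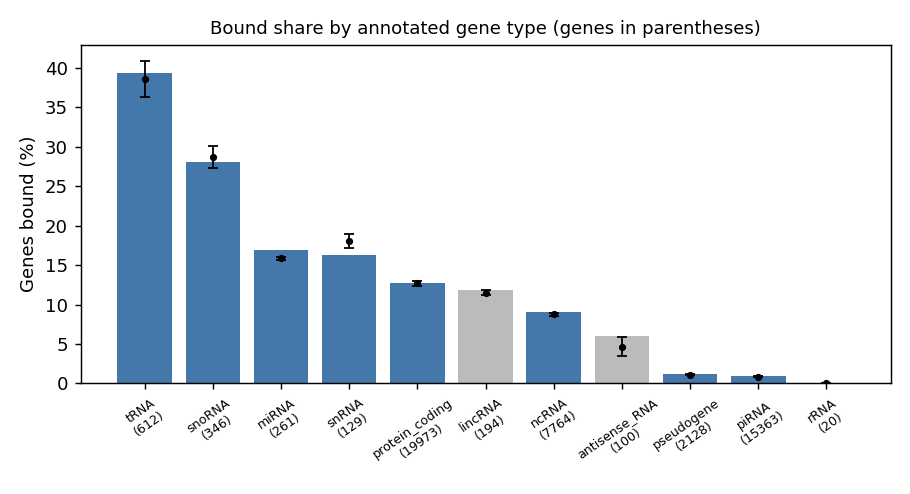
Share of genes with a point source in the promoter window (y axis, percent) by annotated gene type (x axis, number of genes in parentheses), for the IDR list (bars, blue where adjusted p is 0.05 or less, grey otherwise) and as mean ± SD over the top regions of the 3 replicates (black points). tRNA genes stand highest at 39.4% and piRNA genes at 0.905%.

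In the IDR list, the share of bound protein-coding genes on X did not differ from that on the autosomes past the threshold. The shares were 13.8% (376 of 2731) on X and 12.5% (2154 of 17242) on autosomes, an odds ratio of 1.12 (95% interval 0.994 to 1.26, two-sided Fisher's exact p = 0.063). Chromosomes III (18.5%) and I (17.2%) lay above X, and chromosomes IV (11.6%), II (10.6%) and V (8.45%) below it. Each replicate's own list gave a higher share on X, with odds ratios of 1.14 (Fisher's exact p = 0.034), 1.17 (p = 0.0094) and 1.17 (p = 0.0073) for replicates 1, 2 and 3. The difference was not seen when the chemoreceptor, lectin and F-box families were left out (odds ratio 1.01, exact p = 0.88). Circular shifts along the gene order, which allow for neighbouring genes that are bound together, gave a permutation p = 0.82 for the IDR list. For replicates 1, 2 and 3 they gave a permutation p of 0.83, 0.79 and 0.76. The wide spread of bound shares between whole chromosomes leaves the shifts little power here. By region, X took 34 of the 100 nuclear regions with the highest scores although it makes up 17.7% of the nuclear genome. X regions lay in promoters less often than autosomal regions, 34.0% (366 of 1076) against 44.1% (1823 of 4133; two-sided Fisher's exact p = 1.9e-09, a comparison chosen after the regions were seen). X holds 13.7% of the nuclear protein-coding genes, so its promoters are sparser than its length would give, and this comparison does not allow for that.

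**Figure D4:**
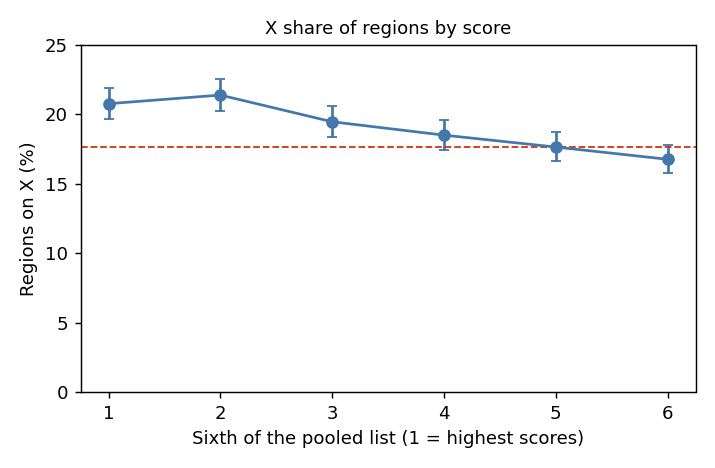
Share of regions on X (y axis, percent) in sixths of the pooled relaxed list ordered by score (x axis, 1 holds the highest scores), with 95% Wilson intervals that cover counting error only; the dashed line is the share of X in the nuclear genome, 17.7%. The share lies at 20.8% in the highest-scoring sixth and at 16.8% in the lowest.

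The sequence under MEP-1 point sources was rich in GA repeats and in overlapping 6-mers around GACGCAG. GAGAGA (reverse complement TCTCTC) occurred in 26.3% of the 100 bp windows at 5209 point sources and in 5.61% of flanks 500 bp away (exact McNemar test with Benjamini-Hochberg adjustment over 2080 6-mers, adjusted p = 1.2e-181). AGAGAG followed with 22.4% against 4.57% (adjusted exact p = 9.4e-161), CGTCTC with 16.03% against 2.78% (2.4e-123), AGAGAC with 17.6% against 3.71% (4.0e-117) and ACGCAG with 13.5% against 2.05% (3.3e-114). The most depleted were AAAATT, in 19.1% against 42.6% (9.1e-144), and AAAAAT, in 27.5% against 49.0% (6.5e-109). In all 738 6-mers were enriched and 617 depleted. The point sources were richer in G and C than their flanks, 43.7% against 35.9% (two-sided permutation p = 1e-05, the smallest that 100000 sign flips can give). Against copies of the same windows shuffled with their dinucleotides kept, 359 6-mers were enriched, 264 of them also enriched against the flanks, and 711 were depleted. GAGAGA stood at 26.3% against 12.9% there, while AAAATT and AAAAAT were no longer depleted (ratios 1.04 and 1.29). The 2189 promoter points were also set against unbound promoters at the same TSS distance, a control added after the data were seen. The smallest adjusted p was then that of GAGCGC, in 13.6% against 1.23% (exact McNemar test, adjusted p = 7.5e-56). ACGCAG stood at 15.4% against 2.28% in that control and GAGAGA at 22.6% against 6.81%. The order of the 6-mers thus depended on the control.

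The strain carries an added mep-1 transgene and an unc-119 marker, so the regions around both loci were counted. Within 20 kb of mep-1, replicates 1, 2 and 3 listed 13, 16 and 12 relaxed regions, which put mep-1 at percentiles 58.5, 67.4 and 53.1 of all protein-coding genes (mean 59.7 ± 7.19, SD, n = 3). Within 20 kb of unc-119 the percentiles were 44.8, 64.3 and 36.6 (mean 48.6 ± 14.2). In the IDR list, mep-1 had 4 regions within 20 kb (percentile 79.5) and unc-119 had 5 (86.8), and within 10 kb the same regions put them at 92.4 and 96.1. Within 50 kb, the mean percentile of mep-1 over the 3 replicates was 92.8 and that of unc-119 was 58.9. In the IDR list they lay at 93.3 and 69.0.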

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

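The tests of transcription and of the X motif named below and in the part on other observations were chosen after the results were seen. The bounds for those of the X share and of the tagged locus were set before their results were seen, although the background without large families and the lists of single replicates, with their circular shifts, were added to the tests of X after the data were seen.

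Mitochondrial DNA entered the region counts, the overlaps between lists and an alternative promoter share, but none of the other tests. It held 20 regions of the optimal IDR list, among them the region with the highest score of that list, 5182. Replicates 1 and 2 listed 25 and 23 mitochondrial regions and replicate 3 listed 0. No explanation was tested.

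The share of bound genes on X lay above that on autosomes in each replicate's list, and in the IDR list the same difference did not pass. Circular shifts, which do not treat neighbouring genes as independent, gave a permutation p = 0.82 for the IDR list and of 0.76 to 0.83 for the 3 replicates. By that test the difference was not beyond chance. Bound shares ranged from 8.45% on chromosome V to 18.5% on III, far wider than between X and autosomes. The test therefore has little power here and does not show chance as the source. A single replicate as its source is argued against, since the lowest of the 3 odds ratios was 1.14 (mean 1.16 ± 0.021, SD, n = 3) and each passed Fisher's exact test. Whether X coverage rose uniformly over the control cannot be told from the X share along the pooled list. X took 16.8% of its lowest-scoring sixth (95% interval 15.7 to 17.8) and 20.8% of the highest (19.7 to 21.9). A rise that lifted every X score would move X regions up the list, so it could give the same order. These shares are also of regions and not of bound genes. Autosomal gene families that are rarely bound may account for the difference per gene, since the odds ratio of the IDR list fell from 1.12 to 1.01 without them. The 95% interval of the latter, 0.897 to 1.14, spans 1, which goes with this explanation. It also holds 1.12, so the question stays open. No biological explanation was tested for the per-gene share.

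The promoter of mep-1 was bound in a strain with added copies of mep-1. Extra copies may add regions around mep-1 and unc-119. Within 20 kb, the highest percentile of the region count over both genes and the 3 replicates was 67.4, below the bound of 75 set to count against extra copies. That bound was too narrow, since it left out the IDR list and the other distances. In the IDR list mep-1 and unc-119 lay at 79.5 and 86.8 within 20 kb and at 92.4 and 96.1 within 10 kb. Over the replicates mep-1 lay at means of 79.5 and 92.8 within 10 kb and 50 kb, while unc-119 lay at 72.4 and 58.9. The pooled list gave 45.7 and 56.0 within 20 kb. The lists do not give the length of the added sequence, and the count says nothing on the height of a region, so extra copies cannot be told apart from binding at these loci. No biological explanation was tested.

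Bound promoters were most frequent at ribosomal protein (80.7%), translation (65.0%) and proteasome genes (57.6%), classes that are strongly transcribed in most cells. At 50% each followed the respiratory chain genes and a list of regulators, that of DREAM and synMuv B genes. A signal that follows strong transcription whatever protein is tagged could give such a list. Collagen genes, strongly transcribed in the epidermis of larvae, were bound at 3.95%, which would count against it only if their transcription per nucleus were known. The major sperm protein genes stood at 0%, but as near-identical copies whose call was lost under 12 of 16 alternatives they weigh little. tRNA genes (39.4% bound) and snoRNA genes (28.0%), which are strongly transcribed too, go with it. The larvae were whole animals and no expression values were analysed here, so transcription per nucleus is unknown and the explanation cannot be told apart from binding by MEP-1. A precipitation against GFP alone would bear on it.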

How the results depend on the processing

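Alternatives were chosen before the data were examined, except the single-replicate lists for promoter share, gene types, gene lists and X, circular shifts of X in those lists, the backgrounds without large families and without piRNA genes, genes with no same-strand neighbour upstream, the mitochondrial denominator and the unbound-promoter control for 6-mers, which were added after seeing the data. The promoter share stayed above chance under all 12 tested alternatives (24.2% to 53.8%) and was 41.9% with the mitochondrial regions counted. The score difference of promoters kept its direction and passed under all 7 (0.13 of the range on ranks, and 0.16 to 0.26 on the log2 scale). Of 384 list and 142 gene type comparisons, 347 and 135 kept their side of the threshold. No list call was reversed, and 1 gene type call was, that of other ncRNA genes without the piRNA genes. Lists that did not pass could change direction among the 347, as the muscle list did with the narrow window (odds ratio 0.326 against 1.38).

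The upper part of the IDR list holds 2614 regions by construction. Replicate agreement was 70.9% with overlap of at least 50% of the shorter region, 63.97% for point sources within 100 bp, 75.1% over the top 1000 regions, 68.5% over all relaxed regions, and 71.7% to 74.9% without each replicate. The lists bound more often numbered 6 with the narrow promoter window. Without piRNA genes the odds ratio of other ncRNA genes turned to 0.69, because the background lost its rarely bound part. X passed Fisher's exact test with the wide window (odds ratio 1.12, exact p = 0.047), with overlap of the region (1.12, p = 0.045), with regions of all 3 replicates (1.16, p = 0.037), without each replicate in turn (1.15 to 1.18) and in each replicate's list (1.14, 1.17 and 1.17), and lay at 0.963 with the narrow window, while circular shifts gave a permutation p = 0.82 for the IDR list and 0.76 to 0.83 for single replicates. The mep-1 percentile was 79.5 at 10 kb, 92.8 at 50 kb and 45.7 in the pooled list, and that of unc-119 was 72.4 at 10 kb. Against shuffled windows 359 6-mers were enriched and 711 depleted, and AAAATT and AAAAAT turned to ratios of 1.04 and 1.29. The cause of the other shifts was not tested. Because read depth is unknown, depth limits could not be set for a replicate.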

Other observations

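The test of the X motif, the 9-mer count, the comparison of TSS distances and the tRNA counts were all chosen after the regions were seen.

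The 5 strongest regions on X lay outside the promoters of protein-coding genes. The highest was at 14525467 to 14526316 (score 1663, rank 3 of the nuclear regions), followed by 11093810 to 11094487 (1584), 9465563 to 9466171 (1455), 2996740 to 2997491 (1386) and 6296247 to 6296960 (1341), with the nearest protein-coding TSS 739, 4000, 2513, 2646 and 3356 bp away. All 5 were among the top regions of all 3 replicates. Of the 34 X regions among the 100 nuclear regions with the highest scores, 9 lay in protein-coding promoters (26.5%), against 49 of 66 on autosomes (74.2%, two-sided Fisher's exact p = 5.8e-06).

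A hypothesis is that these are recruitment elements on X of the dosage compensation complex, which lowers the expression of X genes in hermaphrodites and is loaded at sites with a DNA motif. The consensus used for it, TCGCGCAGGGAG, was taken from general knowledge and was not checked against a source, and every count below rests on it. Among the 100 highest-scoring regions, 13 of 34 on X (38.2%) held this motif with at most 2 mismatches in the 200 bp around the point source, against 3 of 66 on autosomes (4.55%, two-sided Fisher's exact p = 3.4e-05), and 0 of the 34 X flanks 1000 bp away did. All 13 lay among the 50 highest-scoring regions, which held 19 X regions, outside protein-coding promoters and in the top regions of all 3 replicates. Of these, 1 is the region upstream of the non-coding gene C18A11.13. Over all 5209 nuclear regions the motif was rarer, in 31 of 1076 on X (2.88%) and 35 of 4133 on autosomes (0.847%, odds ratio 3.47). Most X regions therefore lacked it. Over the whole nuclear genome, 47 of 284 motif matches on X with at most 2 mismatches lay in an IDR region (16.5%), against 49 of 1362 on autosomes (3.598%, two-sided Fisher's exact p = 1.2e-13). IDR regions covered 2.14% of X and 1.74% of the autosomes, so autosomal matches also lay in regions more often than their coverage gives. With at most 1 mismatch the counts were 21 of 32 on X (65.6%) and 1 of 37 on autosomes (2.70%, two-sided Fisher's exact p = 8.2e-09). The result is consistent with signal at recruitment elements, but whether MEP-1 itself is there, or such sites are recovered with any tagged protein, was not tested; a precipitation of MEP-1 after loss of the complex, and one of GFP alone, would tell.

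The 9-mer GAGACGCAG, spelled by overlapping enriched 6-mers, occurred in 7.56% of the windows at point sources and in 0.557% of flanks; it was put together from 6-mers found in these windows, so the shares describe it and test nothing. Its share was similar in promoters (8.18%) and outside them (7.12%), and was 3.62% on X and 8.59% on autosomes.

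The loss of the ribosomal call with the narrow promoter window goes with the position of these point sources. Where the ribosomal gene was the nearest, 41 genes had a median distance of 268 bp, against 173 bp for 2047 other genes, and 36 of the 41 (87.8%) lay more than 200 bp away, against 842 of the other genes (41.1%). These values describe what the window already showed and are no separate test. tRNA genes were bound at similar rates on X and autosomes, 41.3% (114 of 276) and 37.8% (127 of 336; two-sided Fisher's exact p = 0.41), and 217 point sources lay in a tRNA window, 188 of them outside protein-coding promoters.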
